A study of Mus musculus with 12 samples.

How the data were processed

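Total RNA of 12 liver samples was extracted with the RNeasy mini kit, and 100 ng of each was amplified with the Ambion WT Expression Kit, labelled with the Affymetrix WT Terminal Labeling Kit and hybridised to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The mice were male, of C57BL/6 background and 8 to 10 weeks old at the start, per the labels. Groups were taken from the labels: wild-type control, wild-type ethanol, null control and null ethanol, with 3 arrays each and 1 sample per array.

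The deposited values are 1 summarised intensity per probe set and array, normalised between arrays by the authors with RMA, per the submitters' processing notes. The software, its version and the background settings are not given in the sources used here. The deposited intensity values ran from 1.816 to 20156, so they were on the linear scale, and log2 was taken here. Array medians after log2 lay between 5.55 and 5.62, and no array column was left out. The genome build of the probe set annotation is not given in the sources used here.

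Of 41345 probe sets, 25335 were listed with a gene, 23521 of these with exactly 1 gene and 1814 with several genes, and 16010 had no gene listed. Probe sets naming exactly 1 gene were used, 1 per gene (the 1 with the highest mean over the 12 arrays), which gave 22151 genes, of which 1106 had more than 1 probe set. Of the probe sets naming 1 gene, 23328 were matched to the RefSeq annotation of GRCm38.p6 by Entrez ID, and 0 symbols changed. This annotation was used only for names and for which genes neighbour each other. A gene was tested if its value lay above the 40th percentile of gene-level values of its array on at least 3 arrays; the percentile lay between 5.61 and 5.72 on the log2 scale, and 14013 genes were tested. Probe sets with several genes or none were tested apart, with the same filter and fit. A gene below the filter is read as dim, not as absent.

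One linear model with a mean per group was fitted to all 12 arrays with limma (lmFit, contrasts.fit and eBayes, no trend, not robust), with 8 residual and 4.95 prior degrees of freedom. There were 7 contrasts: ethanol against control in each genotype, null against wild-type on each diet, the interaction, ethanol averaged over the genotypes and genotype averaged over the diets. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within the contrast. The median standard error of a log2 change was 0.116 for a pair of groups, 0.082 for the averages and 0.164 for the interaction. No replicate number was used as a block because no label gives it a meaning.

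The genes named in the text were chosen by rule: the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (without the overlap condition for the interaction and the averages), the 10 genes with the smallest p where fewer than 5 passed, up to 4 members with the smallest p of each gene list described, and Ppard, Cyp2b10, Cyp2e1, Angptl4, Pdk4 and Pdxk throughout. Predicted genes, clone names, microRNAs, snoRNAs and olfactory and vomeronasal receptors were counted but not named by this rule. There were 40 gene lists with 671 entries, of which 599 were on the array and 72 were not; several genes are in more than 1 list, and most markers of non-hepatocytes have some expression in other liver cells. The lists covered ethanol and lipid metabolism, targets of nuclear receptors, stress responses, inflammation, cell types of the liver, the clock, sex-biased genes and zones of the lobule. A list with at least 5 measured members (35 lists) had a set test with camera (limma) at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of the contrast, and again with an estimated correlation. With the estimated correlation 0 lists passed in any contrast. Comparisons, gene lists, the rule for named genes, and alternatives were written down before the data were examined, except where a later choice is named.

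The order of genes along chromosome 17 gave a one-sided Fisher exact test of genotype calls among the 200 tested genes on each side of Ppard. Pearson's and Spearman's correlations were taken across genes. Splits of the arrays were counted in full (10 splits of 3 against 3 arrays) or as 100 drawn with a fixed seed within the levels of the other factor.

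The steps were tested on simulated data, drawn for the 14013 genes from normal distributions with each gene's mean and within-group SD, independent between genes, with 50 genes changed at each fold size. Real genes are correlated, so these shares are not a bound for the real arrays. The Benjamini-Hochberg threshold is also looser where more genes are called. The simulations called 182 genes for ethanol in either genotype and 134 for the interaction, and 213 for ethanol averaged. The real arrays gave 13 in wild-type mice, 1 in null mice, 2 for the interaction and 2 for ethanol averaged. Recovery in these comparisons was thus likely lower than the shares below. At 1.5-fold 56% of the changed genes were recovered for ethanol in wild-type mice, 60% for ethanol in null mice, 68% for genotype on control diet, 52% for genotype on ethanol diet, 14% for the interaction, 90% for ethanol averaged over the genotypes and 86% for genotype averaged over the diets. At 2-fold the shares were 96%, 92%, 86%, 90%, 68%, 100% and 100% in the same order. At 3-fold they were 98%, 100%, 98%, 100%, 90%, 100% and 98%, and at 4-fold 98%, 98%, 98%, 100%, 94%, 100% and 100%. Unchanged genes called numbered 8, 7, 9, 10, 1, 18 and 15. A simulated rise of 0.5 in the cholesterol synthesis list gave a camera adjusted p of 7.39e-32 (8.3e-05 with an estimated correlation), with 0 other lists called. As the simulated genes were independent, this cannot show whether correlation between real genes makes lists pass at the preset correlation.

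Alternatives were: no filter or a filter at the 60th percentile, a second quantile normalisation or centring of each array on its median, the replicate number as a block, only the groups compared in the fit, eBayes with trend and robust set, array weights, the mean of all probe sets of a gene, an unadjusted p under 0.05 with a 1.5-fold change, an adjusted p under 0.1, an estimated correlation for the lists, and each of the 12 arrays left out in turn. After the data had been seen, 2 more were added: wild-type control 2 and null ethanol 3 left out together, and snoRNA genes left out. Fits with only the groups compared were not run for the interaction and the averages, which use all 4 groups.

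R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.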

Results

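Liver RNA of male mice was measured on Affymetrix Mouse Gene 2.0 ST arrays, which carry probes along whole transcripts. Wild-type mice and mice null for Ppard, the gene of the nuclear receptor PPARβ/δ, had been fed a liquid control diet or a liquid diet with 4% (v/v) ethanol for 16 weeks, per the labels. The 4 groups (wild-type control, wild-type ethanol, null control, null ethanol) held 3 arrays each, and this number of arrays limits the precision of every value. The labels name 10 mice per group in the feeding study and give each array a sample of its own, without saying that each is a separate mouse, so errors and p-values measure the spread between these samples. Median log2 intensity lay between 5.55 and 5.62 on the 12 arrays. The first principal component held 32.3% of the variance and separated the genotypes. Values are log2 changes with standard errors from limma, with 3 arrays per group, and adjusted p-values are from limma over 14013 genes.

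Ppard had similar intensities in all 12 arrays. The log2 intensities were 7.64, 8.01 and 7.68 in the wild-type control arrays, 7.96, 7.77 and 7.85 in the wild-type ethanol arrays, 7.69, 7.91 and 7.91 in the null control arrays, and 7.88, 7.93 and 8.06 in the null ethanol arrays. Group means were 7.78 ± 0.20, 7.86 ± 0.10, 7.84 ± 0.13 and 7.96 ± 0.09 (SD, n = 3). The genotype difference was 0.08 ± 0.08, with a 95% confidence interval from -0.09 to 0.25 (limma adjusted p = 0.621). A second probe set, which also names 1810013A23Rik, had group means of 5.94, 6.04, 6.01 and 6.30 and was not lower in null arrays either. Where the probes lie relative to the disrupted part of the gene is not given in the sources used here, so Ppard checks no genotype label.

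The comparison of ethanol with control diet in wild-type mice addressed which liver transcripts 16 weeks of ethanol change when PPARβ/δ is present. Blvrb, which encodes a biliverdin reductase, rose 1.53-fold (log2 change 0.61 ± 0.10, limma adjusted p = 0.042), from 8.76 to 8.87 in the 3 control arrays to 9.39 to 9.43 in the 3 ethanol arrays. Tmem86a, which encodes a lysoplasmalogenase, rose 1.47-fold (0.56 ± 0.09, adjusted p = 0.0481), and Fyttd1, which encodes an mRNA export adaptor, fell by 0.57 ± 0.09 (adjusted p = 0.042). Cyp2b10, a cytochrome P450 controlled by the receptor CAR, was 2.95-fold higher with ethanol (1.56 ± 0.43) but did not pass (adjusted p = 0.146), and its arrays spanned 4.96 to 5.65 on control diet and 6.52 to 7.52 on ethanol. Its control arrays lay near or below the filter (5.61 to 5.72), so background limits its fold. Groups of 3 and 3 arrays fail to overlap by chance for 10% of genes. Cyp2e1, the ethanol-oxidising cytochrome P450, differed by -0.02 ± 0.07, Ppard by 0.08 ± 0.11, Angptl4 by 0.25 ± 0.22, Pdk4 by 0.34 ± 0.30 and Pdxk by 0.23 ± 0.14, and none of these 5 passed.

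Of the 35 gene lists with a set test, 4 passed in wild-type mice on ethanol, although none of their members passed alone. PPARα targets lay higher (15 of 16 positive, median 0.28, 0 passed over all genes and 1 higher adjusted over the list alone; camera adjusted p = 0.00102), among them Acot2 at 0.89 ± 0.22 and Cidec at 1.13 ± 0.38. With an estimated correlation that list had an adjusted p = 0.728. Cholesterol synthesis genes lay lower (17 of 19 negative, median -0.23, 0 passed and 2 lower adjusted over the list alone; adjusted p = 0.00156), with Msmo1 at -1.26 ± 0.34 and Sqle at -1.52 ± 0.49, and adjusted p = 0.736 with an estimated correlation. Interferon-stimulated genes lay lower (17 of 20 negative, median -0.27, 0 passed in either count), with Rtp4 at -0.64 ± 0.21. Adjusted p was 0.0108 with camera and, with an estimated correlation, adjusted p was 0.744. Without wild-type control 2 that list's median was -0.07 and it did not pass. Oxidative phosphorylation genes lay higher (17 of 24 positive, 0 passed and 2 higher adjusted over the list alone), with Cox4i1 at 0.42 ± 0.12. Adjusted p was 0.0423 with camera and, with an estimated correlation, adjusted p was 0.728. Of 11 ethanol and acetaldehyde metabolism genes 0 passed, and 1 was lower adjusted over the list alone. Of 15 CAR targets 0 passed, and 2 were higher adjusted over the list alone.

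Limma called 13 of 14013 genes in this comparison, 12 higher and 1 lower, with 2034 at an unadjusted p under 0.05 where chance gives 701. Small nucleolar RNAs (snoRNAs, short RNAs that guide rRNA modification) made up 9 of the 12 higher genes, and the median of 70 snoRNAs was 7.39, 7.90 and 7.37 in the wild-type control arrays against 8.57, 8.65 and 8.42 in the wild-type ethanol arrays. The count was 812 (316 higher, 496 lower) without wild-type control 2, 32 without null ethanol 1, and 20 without null ethanol 3. It was 6 without null control 3, 5 without null control 1, 4 without null control 2 or null ethanol 2 and 3 without wild-type control 1. It was 2 without wild-type control 3, wild-type ethanol 1 or wild-type ethanol 3, and 0 without wild-type ethanol 2. Blvrb, Tmem86a and Fyttd1 stayed called without wild-type control 2, null ethanol 1 or null ethanol 3 and lost the call without any of the other 9 arrays. Over the 12 fits Blvrb lay between 0.59 and 0.64, Tmem86a between 0.49 and 0.61 and Fyttd1 between -0.63 and -0.51. With snoRNA genes left out, an alternative chosen after the data had been seen, Blvrb, Tmem86a and Fyttd1 lost the call (each adjusted p = 0.109).

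**Figure D1:**
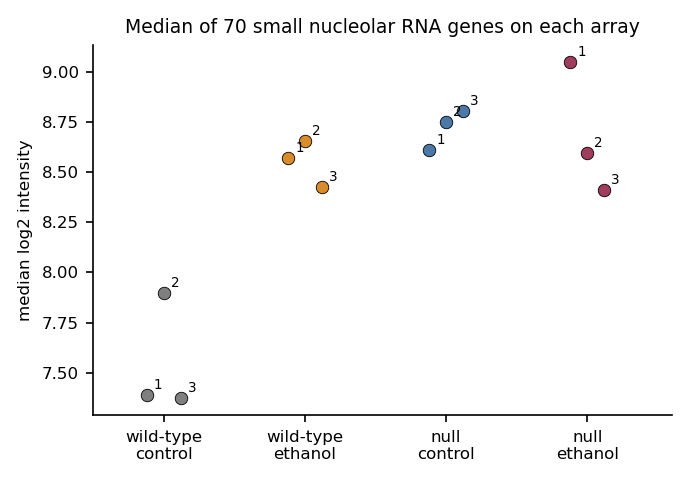
Median log2 intensity of 70 snoRNAs on each array (points, with the replicate number) by group. The 3 wild-type control arrays lie at 7.39, 7.90 and 7.37, and the other 9 arrays lie between 8.41 and 9.05.

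**Figure D2:**
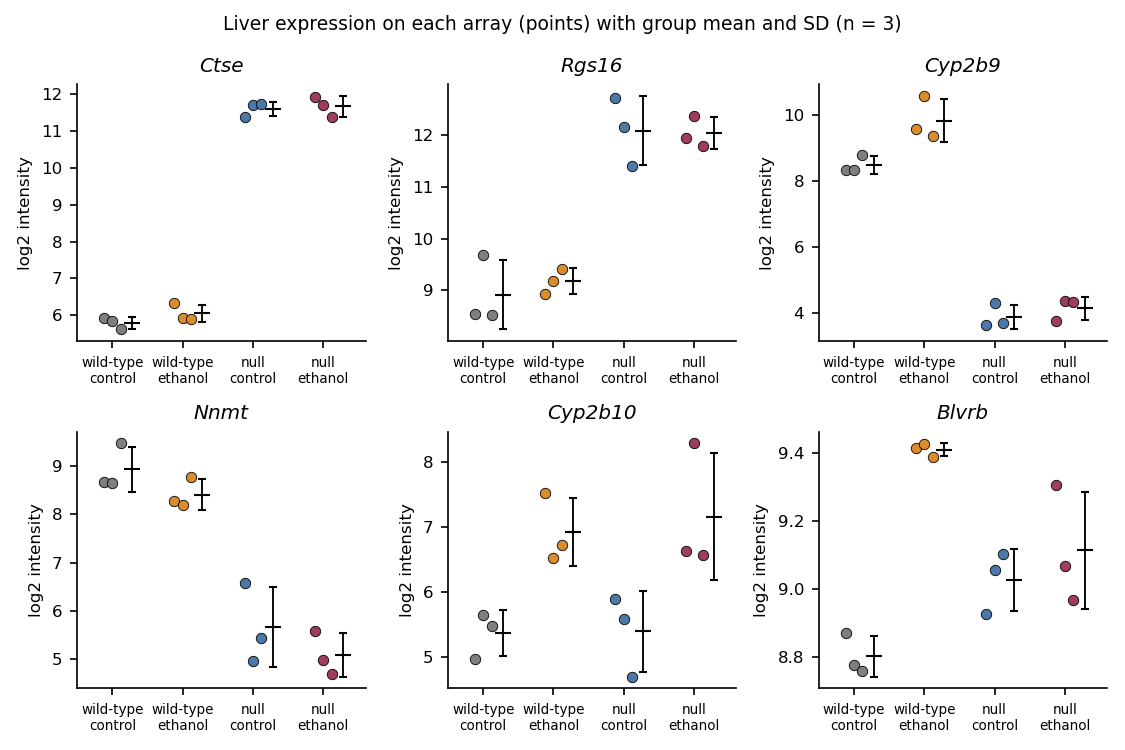
Log2 intensity of Ctse, Rgs16, Cyp2b9, Nnmt, Cyp2b10 and Blvrb on each array (points) by group, with the group mean and SD (n = 3 arrays). Ctse lies between 5.61 and 6.32 in the wild-type arrays and between 11.37 and 11.93 in the null arrays, and Cyp2b10 lies between 4.69 and 5.89 on control diet and between 6.52 and 8.28 on ethanol.

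The comparison of ethanol with control diet in null mice addressed the same question in the absence of PPARβ/δ. Gca, which encodes the calcium-binding protein grancalcin, fell by 0.97 ± 0.12 (1.95-fold, limma adjusted p = 0.0387), from between 7.63 and 8.07 to between 6.80 and 6.99. Cyp2b10 was 3.41-fold higher with ethanol (1.77 ± 0.43) but did not pass (adjusted p = 0.248), with arrays from 4.69 to 5.89 on control diet and from 6.56 to 8.28 on ethanol, and background limits this fold as well. The other genes with the smallest p-values were Polr2l at -0.60, Mef2d at -0.62, Gask1a at -0.72, Ube2u at -0.92, Kcnj8 at -0.48, Dusp1 at -1.26, Gstm6 at -0.54, Dapk1 at -0.63 and Rassf3 at -0.62, with adjusted p from 0.144 to 0.179, and none of them passed. Cyp2e1 differed by 0.04 ± 0.07, Ppard by 0.12 ± 0.11, Angptl4 by -0.08 ± 0.22, Pdk4 by -0.50 ± 0.30 and Pdxk by -0.05 ± 0.14.

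In null mice on ethanol 4 lists passed the set test, again with 0 members passing over all genes. Macrophage and Kupffer cell markers lay higher (16 of 19 positive, median 0.30, 0 adjusted over the list alone; camera adjusted p = 1.87e-06), with Cd5l at 0.47 ± 0.16 and Csf1r at 0.47 ± 0.20, and adjusted p = 0.954 with an estimated correlation. The median of the macrophage markers was 0.15 without null control 2 and 0.15 without null ethanol 3, where the list still passed. Interferon-stimulated genes lay lower (17 of 20 negative, 0 adjusted over the list alone), with Oasl1 at -0.78 ± 0.25. Adjusted p was 0.0204 with camera and, with an estimated correlation, adjusted p was 1. Fibrosis and stellate cell markers lay lower (17 of 20 negative, 0 adjusted over the list alone), with Timp2 at -0.35 ± 0.10 and Mmp2 at -0.51 ± 0.16. Adjusted p was 0.0233 with camera and, with an estimated correlation, adjusted p was 0.99. Male-biased liver genes lay lower (12 of 13 negative, 4 adjusted over the list alone), with Hsd3b5 at -2.08 ± 0.48 and Cyp4a12b at -1.45 ± 0.33. Adjusted p was 0.0233 with camera and, with an estimated correlation, adjusted p was 0.954. Beside Gca, limma called 0 further genes, with 1709 at an unadjusted p under 0.05. The count was 3 without null control 3, 2 without wild-type control 3, and 0 without wild-type ethanol 1, 2 or 3 or null control 2. Gca lost its call without those 4 arrays and without null control 1 or null ethanol 1, 2 or 3 (-0.85 to -1.07 over the 12 fits).

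The interaction asked whether the ethanol effect differed between the genotypes. Limma called 2 of 14013 genes, both snoRNAs, which the rule for naming genes leaves out and which were named after their values were seen. Snord53 differed by -1.80 ± 0.24 and Snord111 by -1.55 ± 0.22 between the ethanol effects in null and wild-type mice (both adjusted p = 0.0483). Snord53 was 1.52 higher and Snord111 0.97 higher with ethanol in wild-type mice, and they differed by -0.29 and -0.58 in null mice. The next genes by p were Zfp707 at -0.89, Tet2 at -0.96, Tob1 at -0.89, Trav12-2 at 0.85, Ddx39a at -0.72, Rogdi at -0.96, Alkbh7 at -0.70, Mcc at -0.72, Tmem9 at -0.74 and Agxt, a glyoxylate-detoxifying transaminase, at -0.89, all with adjusted p = 0.17 and none called. The interaction of Cyp2b10 was 0.21 ± 0.61 (95% confidence interval -1.10 to 1.52), that of Cyp2e1 0.06 ± 0.10, of Ppard 0.04 ± 0.16, of Angptl4 -0.33 ± 0.30, of Pdk4 -0.84 ± 0.43 and of Pdxk -0.28 ± 0.19. None of the 35 lists passed with camera, where PPARα targets had the smallest set p (adjusted p = 0.0887, 12 of 16 negative, 0 passed and 2 lower adjusted over the list alone). In this comparison 2107 genes had an unadjusted p under 0.05, and the count was 84 without wild-type control 2, 5 without null ethanol 1, 2 without null ethanol 3 and 0 without any of the other 9 arrays.

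Averaged over the genotypes, Gca fell with ethanol by 0.72 ± 0.09 (1.65-fold, limma adjusted p = 0.0206). The snoRNA Snord71, the second of 2 calls and also named after its value was seen, was higher. The median snoRNA change with ethanol was 0.87 in wild-type and 0.04 in null mice, so the average largely carries the low wild-type controls. As many genes were called in 12 of 100 splits of the labels, so chance is not excluded for these 2 calls. Cyp2b10 was 3.17-fold higher with ethanol (1.67 ± 0.30), a fold that background on control diet limits, but did not pass (adjusted p = 0.0945). Without wild-type control 2 its change was 1.74 with adjusted p = 0.034, where the alternatives ranged from 0.023 to 0.25. The next genes by p were Ube2u at -0.75, Tsc22d1 at -0.73, Polr2l at -0.42, Rabggtb at 0.89, Mup21 at -0.94, H2-Q1 at -0.69, Vldlr, a lipoprotein receptor, at 0.64, Slc2a1, a glucose transporter, at 0.44 and Ints6 at -0.53, with adjusted p from 0.0598 to 0.0945. The second probe sets of Tsc22d1 and Slc2a1 were dim, with group means from 4.98 to 5.02 and from 5.40 to 5.57. Cyp2e1 differed by 0.01 ± 0.05, Ppard by 0.10 ± 0.08, Angptl4 by 0.09 ± 0.15, Pdk4 by -0.08 ± 0.22 and Pdxk by 0.09 ± 0.10.

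Of the lists, 6 passed for ethanol averaged over the genotypes, with 0 members of each passing over all genes. Cholesterol synthesis genes lay lower in all 19 members (median -0.22, 2 lower adjusted over the list alone), with Nsdhl at -0.77 ± 0.20. Adjusted p was 3.6e-05 with camera and, with an estimated correlation, adjusted p was 0.758. The median was -0.15 without null control 2. Macrophage and Kupffer cell markers lay higher (16 of 19 positive, 1 adjusted over the list alone). Adjusted p was 1.72e-05 with camera and, with an estimated correlation, adjusted p was 0.723. Interferon-stimulated genes lay lower (19 of 20 negative, 4 adjusted over the list alone), with Ifih1 at -0.32 ± 0.09. Adjusted p was 4.68e-05 with camera and, with an estimated correlation, adjusted p was 0.758. PPARα targets lay higher (13 of 16 positive, 0 adjusted over the list alone). Adjusted p was 0.0119 with camera and, with an estimated correlation, adjusted p was 0.758. Male-biased liver genes lay lower (11 of 13 negative, 2 adjusted over the list alone). Adjusted p was 0.0166 with camera and, with an estimated correlation, adjusted p was 0.723. Adipocyte markers lay higher (5 of 6 positive, 2 adjusted over the list alone), with Pparg at 0.46 ± 0.12. Adjusted p was 0.0467 with camera and, with an estimated correlation, adjusted p was 0.723. Limma called 2 genes, with 1703 at an unadjusted p under 0.05. The count was 293 without wild-type control 2, 7 without null control 3, 6 without null ethanol 3, 4 without null ethanol 2, 1 without null control 2 and 0 without wild-type control 1 or 3, wild-type ethanol 1, 2 or 3 or null ethanol 1. Gca lost its call without these last 6 arrays (-0.66 to -0.77 over the 12 fits).

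The difference between null and wild-type livers, averaged over the diets, asked how the liver transcriptome differs by genotype. Loss of PPARβ/δ and DNA segments of another strain, if present, cannot be told apart in it, as given below. Ctse, which encodes the aspartic protease cathepsin E, rose 52.7-fold in null livers (5.72 ± 0.11, limma adjusted p = 3.58e-12), from 5.61 to 6.32 in the wild-type arrays to 11.37 to 11.93 in the null arrays. Rgs16, a regulator of G protein signalling, rose 8.12-fold (3.02 ± 0.24, adjusted p = 6.02e-06). Cyp2b9, a cytochrome P450 more abundant in female mouse liver, fell by 5.14 ± 0.20 (35.2-fold, adjusted p = 4.84e-09). Nnmt, the nicotinamide N-methyltransferase, fell by 3.30 ± 0.26 (9.84-fold, adjusted p = 5.42e-06), and Mme, which encodes the peptidase neprilysin, fell by 3.04 ± 0.15 (8.23-fold, adjusted p = 7.12e-08). The other largest rises were Igsf23 (5.31-fold), Prelid2 (5.09-fold), the ion channel gene Asic5 (4.95-fold), Atp10d (4.39-fold), the lipid kinase gene Pik3c2g (4.29-fold), Tcf24 (4.28-fold), Slc6a16 (3.27-fold) and the clock gene Ciart (3.19-fold), with adjusted p from 7.12e-08 to 0.0347. The other largest falls were Zfp982 (13.9-fold), Mug2, a plasma protease inhibitor (13.2-fold), the long non-coding RNA Lncbate1 (4.36-fold), Cyp4a12b (3.62-fold), Mid1 (3.5-fold), Pttg1, which encodes securin (3.44-fold), and Slc15a5 (3.34-fold), with adjusted p from 1.6e-09 to 0.000463. Cyp2b9, Mug2, Cyp4a12b and the Saa and Mup genes belong to families of similar genes. Whether their probes also match other members was not checked, so their values are uncertain as to the member measured. Cyp2b9 lay between 3.64 and 4.38 and Zfp982 between 3.10 and 4.02 in the null arrays, below the filter (5.61 to 5.72), Nnmt lay between 4.69 and 6.57 there, and Ctse lay near the filter in the wild-type arrays, so background limits the folds of these 4 genes.

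Of 19 measured macrophage and Kupffer cell markers 14 fell and 0 rose in null livers (15 fell adjusted over the list alone; median -0.52), with the Kupffer cell genes Cd5l at -0.94 ± 0.12, Marco at -0.73 ± 0.11, Adgre1 (F4/80) at -0.85 ± 0.15 and the lysozyme gene Lyz2 at -0.52 ± 0.10. The camera adjusted p was 3.58e-10 and, with an estimated correlation, the adjusted p = 0.203. The number that fell was 6 without null ethanol 1, 7 without wild-type control 1 or wild-type ethanol 3, 8 without wild-type ethanol 2 or null control 2, and 9 without null control 3. Sinusoidal endothelial cell markers lay lower (12 of 14 negative, median -0.30), with 2 called, Pecam1 at -0.37 ± 0.08 and the angiopoietin receptor gene Tek at -0.47 ± 0.12, and 4 adjusted over the list alone. Adjusted p was 0.00395 with camera and, with an estimated correlation, adjusted p was 0.544. The number of endothelial markers called was 9 without null ethanol 3, 1 without wild-type control 1, wild-type ethanol 2 or null control 3, and 0 without wild-type ethanol 3, null control 2 or null ethanol 1 or 2. Markers of neutrophils (4 measured), T and NK cells (7) and pancreatic acinar cells (4) had 0 members past the threshold in either count. B cell markers had 0 of 7 and cholangiocyte markers 0 of 3, with 1 lower in each adjusted over the list alone. Erythroid markers had 1 of 3 lower, Tfrc at -0.65 ± 0.12, and fibrosis and stellate cell markers 1 of 20 lower, Tgfb1 at -0.40 ± 0.09, with the same numbers adjusted over the list alone. Of the adipocyte markers 2 of 6 fell in either count, the lipid-binding protein gene Fabp4 at -0.43 ± 0.11 and the lipoprotein lipase gene Lpl at -0.59 ± 0.16, where the list's median was 0.01, its mean -0.11 and its set direction down. The number that fell with 1 array left out ranged from 0 to 2 for adipocyte markers and from 0 to 1 for B cell and for cholangiocyte markers.

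Of 21 measured genes of fatty acid and triglyceride synthesis 7 rose and 0 fell in null livers (8 rose adjusted over the list alone; median 0.20), with the pyruvate kinase gene Pklr at 0.84 ± 0.13, the fatty acid synthase gene Fasn at 0.97 ± 0.16, the transcription factor gene Srebf1 at 1.05 ± 0.18 and Gpam at 0.35 ± 0.07. Adjusted p was 3.91e-05 with camera and, with an estimated correlation, adjusted p was 0.203. The number that rose was 4 without wild-type ethanol 3. Of 19 cholesterol synthesis genes 4 rose (10 adjusted over the list alone; median 0.35), namely Fdps at 0.93 ± 0.23, Hsd17b7 at 0.35 ± 0.09, the transcription factor gene Srebf2 at 0.36 ± 0.10 and Fdft1 at 0.37 ± 0.10. Adjusted p was 5.33e-05 with camera and, with an estimated correlation, adjusted p was 0.494. That number was 13 without null control 3, 7 without wild-type control 3, 4 without null ethanol 1, 2 without null ethanol 3, 1 without wild-type ethanol 1 and 0 without any of the other 7 arrays. Of 13 PPARβ/δ targets 1 rose, the hormone gene Fgf21 at 1.15 ± 0.18, and 1 fell, Fabp4. These were also the numbers adjusted over the list alone (camera adjusted p = 0.46). Of 16 PPARα targets 1 rose, Fgf21 (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.215). Leaving out 1 array gave from 1 to 3 that rose for PPARα and from 1 to 2 for PPARβ/δ targets, and from 0 to 1 that fell for both. Angptl4 differed by 0.27 ± 0.15, Pdk4 by -0.42 ± 0.22, Pdxk by 0.25 ± 0.10, Cyp2b10 by 0.13 ± 0.30 and Cyp2e1 by 0.02 ± 0.05, and none of these 5 passed.

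**Figure D3:**
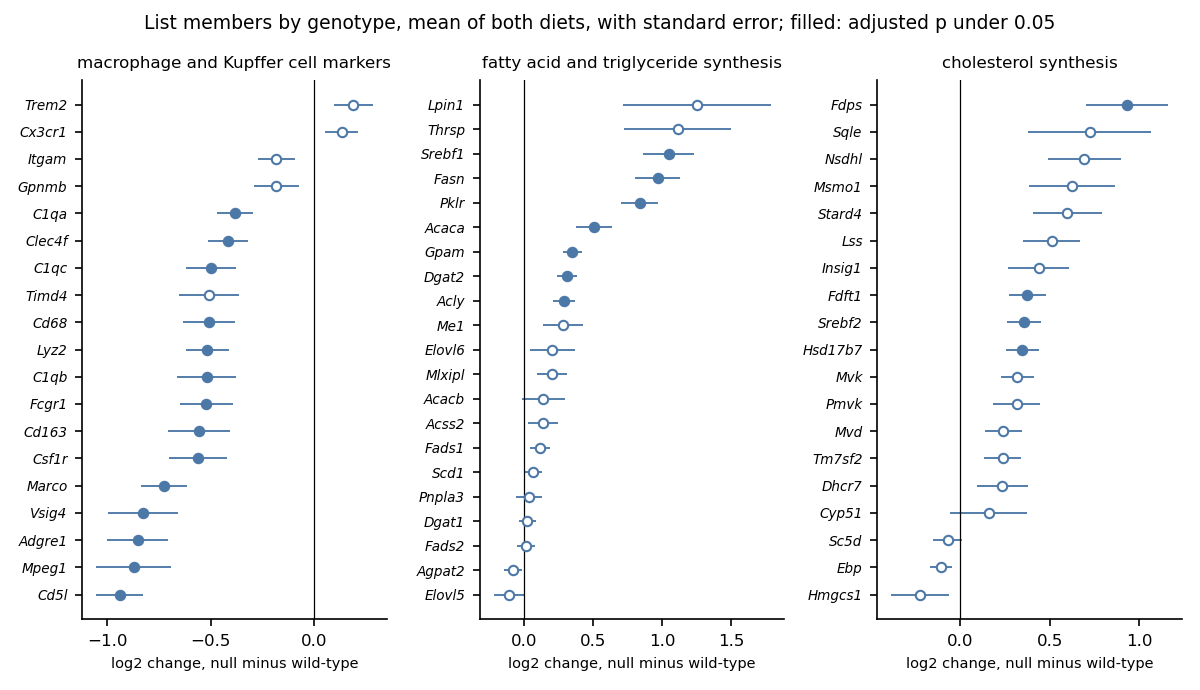
Log2 change between null and wild-type livers, averaged over the diets (x axis), of each measured member of 3 gene lists, with its standard error; filled points have an adjusted p under 0.05. Of 19 macrophage and Kupffer cell markers 14 are filled and lie below 0, and 7 of 21 fatty acid and triglyceride synthesis genes and 4 of 19 cholesterol synthesis genes are filled and lie above 0.

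Of 19 unfolded protein response genes 6 were down and 1 was up in null livers (11 down and 2 up adjusted over the list alone), with the chaperone genes Dnajb9 at -0.61 ± 0.09, Sdf2l1 at -1.04 ± 0.17 and Hspa5 at -0.48 ± 0.08 down and the asparagine synthetase gene Asns at 0.94 ± 0.17 up. Adjusted p was 0.00323 with camera and, with an estimated correlation, adjusted p was 0.391. Male-biased liver genes had 4 of 13 down and 1 up (6 and 1 adjusted over the list alone), with Cyp4a12b at -1.85 ± 0.24, the fatty acid elongase gene Elovl3 at -1.17 ± 0.21 and the complement gene C6 at -0.62 ± 0.14 down and Cyp4a12a at 0.84 ± 0.13 up. Adjusted p was 0.0182 with camera and, with an estimated correlation, adjusted p was 0.412. Periportal hepatocyte markers had 3 of 13 down in either count, the histidine ammonia-lyase gene Hal at -0.72 ± 0.06, Ctsc at -0.48 ± 0.09 and the E-cadherin gene Cdh1 at -1.0 ± 0.24. Adjusted p was 0.0192 with camera and, with an estimated correlation, adjusted p was 0.203. Interferon-stimulated genes lay lower (17 of 20 negative) with 1 called, Zbp1 at -0.80 ± 0.15 (3 adjusted over the list alone). Adjusted p was 0.00323 with camera and, with an estimated correlation, adjusted p was 0.743. Inflammatory cytokines and chemokines lay lower (14 of 20 negative), with Ccl3 at -0.39 ± 0.10 down and the NF-κB inhibitor gene Nfkbia at 0.37 ± 0.08 up (2 and 1 adjusted over the list alone). Adjusted p was 0.0289 with camera and, with an estimated correlation, adjusted p was 0.316. Macrophage and Kupffer cell markers fell in the same comparison as these cytokine and interferon-stimulated genes (14 of 19, median -0.52). Of 17 immediate early genes 2 rose in either count, the phosphatase gene Dusp1 at 1.21 ± 0.16 and the transcription factor gene Egr1 at 0.95 ± 0.23. Adjusted p was 0.0327 with camera and, with an estimated correlation, adjusted p was 0.494. That count was 4 without null control 1, 3 without wild-type control 2, 2 without null ethanol 2 and 1 without any of the other 9 arrays. With 1 array left out the number that fell ranged from 1 to 3 for interferon-stimulated genes, from 0 to 2 for cytokines, from 2 to 4 for periportal markers, from 3 to 4 for male-biased genes and from 5 to 8 for the unfolded protein response.

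Of 16 circadian clock genes 4 rose and 3 fell in null livers (7 and 3 adjusted over the list alone; camera adjusted p = 0.113, not passed). Bhlhe40 at 0.93 ± 0.14 and Per3 at 1.15 ± 0.26 were higher, and Clock at -0.55 ± 0.09 and Arntl (Bmal1), the partner of Clock, at -1.24 ± 0.28 were lower. The number that rose was 2 without wild-type control 2 or 3, wild-type ethanol 2 or 3 or null ethanol 1 or 2.

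Limma called 982 of 14013 genes by genotype averaged over the diets, 423 higher and 559 lower in null livers, with 3005 at an unadjusted p under 0.05. Of the called genes 84 differed at least 2-fold, 38 higher and 46 lower. The count was 621 without wild-type ethanol 3 and 628 without null control 2. Of the 20 genes with the largest changes 19 stayed called without each of the 12 arrays. Slc15a5 and Pik3c2g lay in 1 window of 20 neighbouring tested genes with 11 calls, Mug2 in a window with 10 and Zfp982 in a window with 9, against at most 9 in 200 random orders. Ciart lost its call without wild-type control 1, 2 or 3, wild-type ethanol 1, 2 or 3, null control 2 or null ethanol 1 or 2, at changes of 1.55 to 1.75.

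On the control diet alone, the comparison addressed how the genotypes differ without ethanol. In null livers Ctse rose 56.3-fold (5.81 ± 0.16, limma adjusted p = 2.5e-10), and Rgs16 rose 9.04-fold (3.18 ± 0.34, adjusted p = 0.000189). Igsf23, Prelid2, Atp10d, Pik3c2g, Asic5, Slc6a16, Tcf24 and the MAP kinase phosphatase gene Dusp1 rose between 3.72-fold and 7.23-fold (adjusted p from 8.73e-07 to 0.0318). Cyp2b9 fell 24.3-fold (log2 change -4.60 ± 0.29, adjusted p = 1.28e-06) and Nnmt fell by 3.27 ± 0.36 (9.67-fold, adjusted p = 0.000257). Zfp982, Mug2, the acute phase gene Saa2, Mme, Lncbate1, Pttg1, the muscarinic receptor gene Chrm3 and the urinary protein gene Mup21 fell between 3.63-fold and 11.5-fold (adjusted p from 3.28e-07 to 0.0167). Cyp2b10 differed by 0.03 ± 0.43, Cyp2e1 by -0.01 ± 0.07, Ppard by 0.06 ± 0.11, Angptl4 by 0.43 ± 0.22, Pdk4 by 0.00 ± 0.30 and the pyridoxal kinase gene Pdxk by 0.40 ± 0.14 (adjusted p = 0.108), and none of these 6 passed.

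On the control diet 9 of the 35 lists passed. Macrophage and Kupffer cell markers had 7 of 19 down (14 adjusted over the list alone; median -0.54), with Cd5l at -0.98 ± 0.16 and Mpeg1 at -1.18 ± 0.26. Adjusted p was 3.7e-09 with camera and, with an estimated correlation, adjusted p was 0.316. Fatty acid and triglyceride synthesis had 5 of 21 up (7 adjusted over the list alone), with Fasn at 1.19 ± 0.23, Pklr at 0.89 ± 0.19, Srebf1 at 1.16 ± 0.26 and the ATP citrate lyase gene Acly at 0.48 ± 0.11. Adjusted p was 0.000367 with camera and, with an estimated correlation, adjusted p was 0.316. The unfolded protein response had 4 of 19 down (9 down and 2 up adjusted over the list alone), with Dnajb9 at -0.66 ± 0.13, Hspa5 at -0.54 ± 0.11, Hsp90b1 at -0.45 ± 0.10 and Ddit3 at -0.44 ± 0.12. Adjusted p was 0.00964 with camera and, with an estimated correlation, adjusted p was 0.433. PPARα targets had 3 of 16 up (4 adjusted over the list alone), the acyl-CoA thioesterase gene Acot2 at 1.04 ± 0.22, Fgf21 at 1.18 ± 0.26 and Creb3l3 at 0.33 ± 0.08. Adjusted p was 0.024 with camera and, with an estimated correlation, adjusted p was 0.68. Acute phase proteins had 2 of 21 down in either count, Saa2 at -2.89 ± 0.59 and Saa4 at -1.24 ± 0.26. Adjusted p was 0.0251 with camera and, with an estimated correlation, adjusted p was 0.68. Immediate early genes had 2 of 17 up, Dusp1 at 1.89 ± 0.23 and Zfp36 at 0.96 ± 0.25 (7 adjusted over the list alone). Adjusted p was 0.0251 with camera and, with an estimated correlation, adjusted p was 0.632. Cholesterol synthesis lay higher (17 of 19 positive, 0 in either count). Adjusted p was 0.024 with camera and, with an estimated correlation, adjusted p was 0.68. Inflammatory cytokines lay lower (16 of 20 negative, 0 passed and 3 lower adjusted over the list alone). Adjusted p was 0.024 with camera and, with an estimated correlation, adjusted p was 0.316. Interferon-stimulated genes also lay lower (14 of 20 negative, 0 in either count). Adjusted p was 0.0251 with camera and, with an estimated correlation, adjusted p was 0.68. The macrophage count was 1 without null control 2, 2 without wild-type control 1 and 4 without null control 3. The fatty acid count was 0 without null control 2, 1 without wild-type control 3 or null control 1 and 3 without wild-type control 1 or 2. The unfolded protein response count was 0 without wild-type control 3 or null control 2 and 2 without null control 3. The immediate early count was 6 without wild-type control 2, 5 without null control 1, 2 without null control 2 or null ethanol 3 and 1 without any of the other 8 arrays. With 1 array left out the PPARα count ranged from 0 to 3, the acute phase count from 0 to 3 and the cholesterol synthesis count from 0 to 6.

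Limma called 715 of 14013 genes by genotype on the control diet, 450 higher and 265 lower (62.9% higher), with 3096 at an unadjusted p under 0.05. Of the called genes 136 differed at least 2-fold, 85 higher and 51 lower. Of the 450 higher genes 41 were snoRNAs, whose median was 8.61, 8.75 and 8.80 in the null control arrays against 7.39, 7.90 and 7.37 in the wild-type control arrays. After a second quantile normalisation 355 were higher and 349 lower (50.4% higher). The count was 192 without null control 2, 312 without wild-type control 3, 316 without wild-type control 1 and 1306 without wild-type control 2. Of the 20 named genes 18 stayed called without each of the 12 arrays. Saa2 lost its call without wild-type control 3 (-2.33) or null control 2 (-2.64), and Tcf24 lost it without wild-type control 1, 2 or 3 or null control 2 or 3 (1.53 to 2.12).

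On the ethanol diet alone, the comparison addressed how the genotypes differ under ethanol. In null livers Ctse rose 49.3-fold (5.62 ± 0.16, limma adjusted p = 3.84e-10), and Rgs16 rose 7.28-fold (2.86 ± 0.34, adjusted p = 0.000563). Asic5, Prelid2, Tcf24, Igsf23, Pik3c2g, Atp10d, the deubiquitinase gene Usp2 and the acetoacetyl-CoA synthetase gene Aacs rose between 3.24-fold and 5.73-fold (adjusted p from 8.88e-06 to 0.0234). Cyp2b9 fell by 5.67 ± 0.29 (50.9-fold, adjusted p = 1.34e-07), and Mme fell by 3.66 ± 0.21 (12.6-fold, adjusted p = 6.19e-07). Zfp982, Mug2, Nnmt, Cyp4a12b, Lncbate1, Mid1, Slc15a5 and Aoah, which encodes an enzyme that deacylates endotoxin, fell between 3.4-fold and 16.7-fold (adjusted p from 9.39e-08 to 0.00162). Pdk4 differed by -0.84 ± 0.30 (adjusted p = 0.194), Cyp2b10 by 0.24 ± 0.43, Cyp2e1 by 0.05 ± 0.07, Ppard by 0.10 ± 0.11, Angptl4 by 0.11 ± 0.22 and Pdxk by 0.11 ± 0.14, and none of these 6 passed.

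On the ethanol diet 7 lists passed. Macrophage and Kupffer cell markers lay lower (17 of 19 negative, median -0.44) with 1 called, Cd5l at -0.91 ± 0.16, and 9 adjusted over the list alone. Adjusted p was 3.06e-05 with camera and, with an estimated correlation, adjusted p was 0.613. Cholesterol synthesis lay higher (16 of 19 positive, 0 passed, 8 higher and 1 lower adjusted over the list alone). Adjusted p was 5.81e-05 with camera and, with an estimated correlation, adjusted p was 0.751. Sinusoidal endothelial cell markers lay lower in all 14 members (median -0.33, 0 passed and 2 lower adjusted over the list alone). Adjusted p was 0.00228 with camera and, with an estimated correlation, adjusted p was 0.751. That median was -0.16 without null ethanol 2 and -0.60 without null ethanol 3. Fatty acid and triglyceride synthesis lay higher (15 of 21 positive, 0 passed and 3 higher adjusted over the list alone). Adjusted p was 0.00327 with camera and, with an estimated correlation, adjusted p was 0.613. Periportal markers had 2 of 13 down, Hal at -1.0 ± 0.09 and Cdh1 at -1.43 ± 0.33 (3 adjusted over the list alone). Adjusted p was 0.00327 with camera and, with an estimated correlation, adjusted p was 0.201. Male-biased genes had 3 of 13 down and 1 up (6 and 1 adjusted over the list alone), with Cyp4a12b at -2.42 ± 0.33, Elovl3 at -1.49 ± 0.29 and Serpina1e at -0.58 ± 0.13 down and Cyp4a12a at 1.0 ± 0.18 up. Adjusted p was 0.00795 with camera and, with an estimated correlation, adjusted p was 0.613. Interferon-stimulated genes lay lower (18 of 20 negative) with 1 called in either count, Zbp1 at -0.94 ± 0.21. Adjusted p was 0.0254 with camera and, with an estimated correlation, adjusted p was 0.988. With 1 array left out the number that fell ranged from 0 to 3 for macrophage markers, 0 to 8 for endothelial markers, 1 to 3 for periportal markers, 1 to 3 for male-biased genes and 0 to 1 for interferon-stimulated genes.

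Limma called 252 of 14013 genes by genotype on the ethanol diet, 64 higher and 188 lower (25.4% higher), with 2265 at an unadjusted p under 0.05. Of the called genes 71 differed at least 2-fold, 21 higher and 50 lower. After a second quantile normalisation 85 were higher and 146 lower (36.8% higher). The count was 108 without wild-type ethanol 3, 111 without wild-type ethanol 2, 132 without null ethanol 1 and 155 without null ethanol 2. Of the 20 named genes 17 stayed called without each of the 12 arrays. Tcf24 lost its call without wild-type ethanol 2 or 3 or null ethanol 1 or 3 (1.90 to 2.22). Igsf23 lost it without wild-type ethanol 1 or 3 or null ethanol 1, 2 or 3 (1.55 to 2.02), and Usp2 lost it without wild-type ethanol 2 or 3 or null ethanol 1 (1.51 to 1.74).

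**Figure D4:**
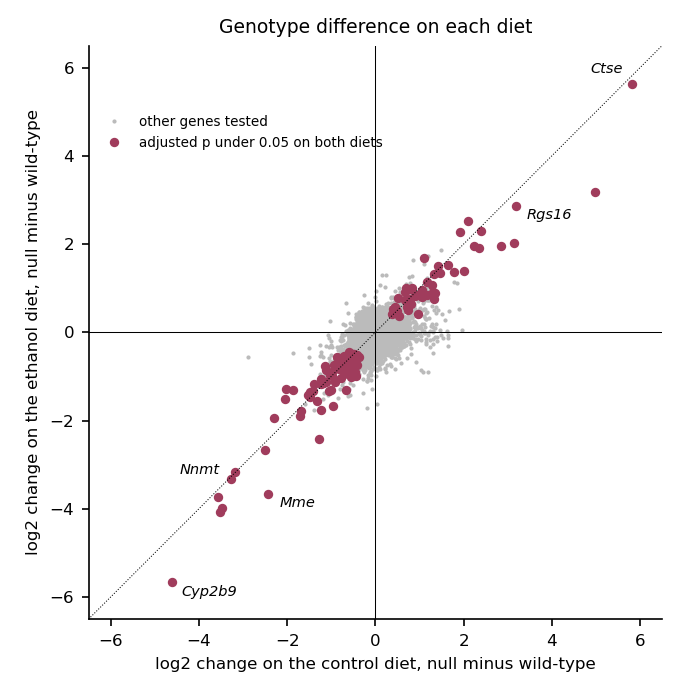
Log2 change between null and wild-type livers on the control diet (x axis) and on the ethanol diet (y axis) for 14013 genes; coloured points passed on both diets. Of these 45 were higher and 81 lower on both diets, with Ctse at 5.81 and 5.62 and Cyp2b9 at -4.60 and -5.67.

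Whether the genotype difference was shared by the diets, and the ethanol effect by the genotypes, was compared across genes on disjoint sets of arrays. Of the genes called by genotype, 45 were higher on both diets (2.06 expected of independent lists), 81 were lower on both (3.56 expected) and 0 moved in opposite directions. Ctse and Rgs16 were among the 45 and Cyp2b9, Nnmt and Mme among the 81. The genotype differences on the diets correlated across the 14013 genes with Pearson's r = 0.497 and Spearman's rho = 0.179, and 53.4% of genes had the same sign. The ethanol effects in wild-type and null mice correlated across genes with r = -0.012 and rho = -0.07, 46.7% of genes had the same sign, and 0 genes were called in both. Genes are not independent replicates, so no p is given for these correlations.

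Whether genes beside Ppard, the targeted gene, were called by genotype more often than others was asked by their order on the chromosome. Of the 200 tested genes on each side of Ppard on chromosome 17, 31 of 400 were called (7.75%), against 951 of 13609 other genes with a position (6.99%; odds ratio 1.118, 95% confidence interval 0.744 to 1.626, one-sided Fisher exact p = 0.305). The order of genes came from the RefSeq annotation of GRCm38.p6. Over 400 genes on each side (624 genes on this chromosome) the odds ratio was 1.326 (p = 0.0329), over the whole chromosome it was 1.281 (p = 0.0446) and over 100 genes on each side 0.695 (p = 0.902), each by the same exact test.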

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

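Chosen only after their results were seen were the tests of PPARβ/δ target genes, of calls off chromosome 17, of an even spread of calls and of the clock arms, and the naming of Snord53 and Snord111. The other tests were chosen before, but leaving out each array for the clock genes used arms formed after the changes were seen. The snoRNAs were likewise taken as a set after the data had been seen, so every test of that set rests on this choice.

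Snord53 and Snord111 were the 2 genes that passed the interaction test, with differences of -1.80 and -1.55 (both limma adjusted p = 0.0483). Chance is not excluded for that count, and snoRNAs were low in wild-type controls, as given below. Snord53 differed more than the other snoRNAs with a host gene. Its mean over the other groups lay 3.725 above wild-type controls, against a median of 1.062 for 54 such snoRNAs. With ethanol Snord53 rose by 1.52 in wild-type mice and differed by -0.29 in null mice. It was thus higher in null than in wild-type livers on the ethanol diet too. Of probe sets left out of the gene-level comparisons, 61 of 5864 with no gene listed (30 higher, 31 lower in null livers) and 102 of 1031 naming several genes (55 higher, 47 lower) were called by genotype averaged over the diets.

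For genotype averaged over the diets, 1 of 100 splits of the genotype labels within diets called as many genes as the real split (982 genes; highest other 20), so a random split of these arrays is excluded as the source of that count. For the interaction 11 of 100 splits and for ethanol averaged over the genotypes 12 of 100 splits called as many genes as the real 2 (highest other 12 in both), so chance cannot be excluded for either. For comparisons of 3 and 3 arrays the 10 splits are too few for a share under 0.05: the real split called 13 genes for ethanol in wild-type mice (highest other 0; 1 split as large), 1 gene for ethanol in null mice (highest other 17; 2 splits as large), 715 for genotype on the control diet (highest other 1; 1 split as large) and 252 for genotype on the ethanol diet (highest other 0; 1 split as large). A split of the null arrays thus called 17 genes where the real split called 1, so chance is not excluded for that call. Whether these arrays hold another structure was not tested.

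Genotype calls clustered along the genome. Calls spread evenly are excluded, since the fullest window of 20 neighbouring tested genes, on chromosome 6 around Slc15a5 and Pik3c2g, held 11 calls against at most 9 in 200 permutations. Segments of another background strain away from chromosome 17 may contribute. There, 84 pairs of neighbouring genes were both called, against a mean of 54.5 and a 95th percentile of 66 in 10000 permutations (permutation p = 2e-04). Among as many top genes for ethanol there were 67 pairs. Pairs whose names share a stem or whose positions overlap were not counted, so pairs of Mug genes are not among the 84. Neighbours can also be regulated together or belong to 1 cell type. Cd163 and Marco, which lie in windows with 10 and 7 calls, belong to the macrophage markers, of which 14 of 19 fell. The windows had no such rule, and Mug genes beside Mug2, whose probes may be shared, count in its window. How much each adds was not tested. DNA travelling with the targeted allele stays open, although the outcomes set down as counting against it came out, because those marks were too weak to exclude it. The odds ratio near Ppard of 1.118 did not pass (one-sided Fisher exact p = 0.305), but its interval from 0.744 to 1.626 includes enrichment. Most calls lay on other chromosomes (920 of 982, 93.7%, against 94.9% of tested genes). These could follow from linked DNA acting in trans, which was not tested. Loss of PPARβ/δ activity, the difference that the design names, and strain segments cannot be told apart for these calls, since such segments, which no table here shows to be present, would lie in the null arrays alike, and the PPARβ/δ target list had a set p of 0.289.

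Of 16 clock genes 4 rose and 3 fell by genotype averaged over the diets (camera adjusted p = 0.113, not passed). The difference between genes that peak with Per and Dbp (9 genes, median 0.47) and genes that peak with Arntl (5 genes, median -0.55) lay between 0.863 and 1.228 without each of the 12 arrays. No single array thus made this difference alone. The calls did depend on single arrays: with 1 array left out from 2 to 5 clock genes rose and from 2 to 3 fell. The difference of 1.018 met the mark set for another clock phase or time of collection (exact p = 0.015 over 2002 splits of these genes into arms). It decides nothing about its source, because the arms were formed after the changes were seen and leave out Bhlhe40 and Cry2. The genes are also not independent. Another clock phase, another time of collection and an effect of PPARβ/δ on the clock stay open. The time of collection is not given in the sources used here.

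SnoRNAs were lower in wild-type controls than in the other 3 groups. Host gene RNA did not differ alike: the median of 42 host genes differed by 0.059 (95% interval 0 to 0.143) against 1.062 for their 54 snoRNAs. The interval comes from resampling host genes and leaves out the spread between arrays. These values met the mark set against transcription of the host genes, but the arrays measure RNA level, so transcription itself is not excluded. Fewer than 3 deviating wild-type control arrays cannot be the whole source, since the highest of the 3 (7.898) lay below the lowest of the other 9 arrays (8.411). All 3 deviating together is not excluded. Within groups, snoRNAs of different hosts rose and fell together with a mean residual correlation of 0.416 (95th percentile of random lists 0.058), which is consistent with recovery of short RNA or labelling that differed between arrays. Whether wild-type controls were handled apart is not given in the sources used here, and a biological difference of this group stays open. With an estimated correlation the 70 snoRNAs had a camera p = 0.0131 for ethanol in wild-type mice, p = 0.0336 for genotype on the control diet and p = 0.0167 for ethanol averaged, but p = 0.0661 for the interaction and p = 0.0619 for genotype averaged.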

How the results depend on the processing

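The alternatives that left out both low-weight arrays together (wild-type control 2, weight 0.352, and null ethanol 3, weight 0.429, against 0.681 to 1.982 for the other 10) and left out snoRNA genes were chosen after the data had been seen. No called gene changed direction; uncalled genes with changes near 0, the median of acute phase genes on the control diet without wild-type control 3, the ethanol correlation and the odds ratio near Ppard did, the last 2 with values below. Of the values of single genes, 2557 kept their side of the threshold under the alternatives other than leaving out 1 array, 44 passed in addition and 190 no longer passed; when 1 array was left out these numbers were 2639, 23 and 554. Only the 40 list tests that passed were followed in this way: over 4 alternatives (both low-weight arrays left out, snoRNA genes left out, the replicate block and the estimated correlation) 104 still passed and 56 did not, and with 1 array left out these numbers were 415 and 65. Lists that passed in addition appear only in the numbers of called lists below. Signal over background limits dim genes, which were not tested below the filter. The median of all genes moved by less than 0.1 (log2) under each scaling. The cause of the changes below was not tested, except that the looser or stricter thresholds and fewer arrays or genes act by their construction.

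Without a filter on dim genes, which tests more genes, calls numbered 7 for ethanol in wild-type mice, 0 for ethanol in null mice, 393 for genotype on the control diet and 1 for the interaction, and the genotype differences on the diets correlated at 0.363. With the stricter filter they numbered 23 for ethanol in wild-type mice and 0 for the interaction, with correlations of 0.064 for ethanol and 0.594 for genotype. Centring on the median gave 33 calls for ethanol in wild-type mice, trend and robust settings gave 24, with 4 for ethanol averaged over the genotypes, and a second quantile normalisation gave 8 for the latter.

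With array weights the calls were 834 for ethanol in wild-type mice, 9 for ethanol in null mice, 1630 and 829 for genotype on the control and ethanol diets, 38 for the interaction, 136 for ethanol averaged and 1865 for genotype averaged, and the genotype correlation was 0.462. With both low-weight arrays left out they were 1089, 0, 1631, 266, 32, 311 and 1383 in that order, with ethanol and genotype correlations of 0.058 and 0.462, and called lists of 2 for ethanol in wild-type mice, 9 for ethanol in null mice, 4 for genotype on the control diet and 2 for the interaction. With snoRNA genes left out limma called 0 genes for ethanol in wild-type mice and 0 for the interaction, against 13 and 2 with them. For ethanol averaged it called 1, against 2 with them. With only the groups compared there were 0 calls for ethanol in null mice and 226 for genotype on the control diet.

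With the replicate number as a block, which pairs arrays by number, calls were 0 for ethanol in null mice and 0 for ethanol averaged, 9 for ethanol in wild-type mice, 613 and 229 for genotype on the control and ethanol diets, 2 for the interaction and 884 for genotype averaged. Residuals of arrays with the same number correlated between -0.145 and 0.191 (median -0.022; 2 of 18 above 0.1). Those of arrays with different numbers correlated between -0.154 and 0.208 (median 0.002), so no pairing by number was seen. Pairing is not excluded, because the groups are small and the residuals within each group sum to 0.

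An unadjusted p under 0.05 with a 1.5-fold change gave 160 calls for ethanol in wild-type mice, 103 for ethanol in null mice, 436 for the interaction, 68 for ethanol averaged and 340 for genotype averaged. An adjusted p under 0.1 gave 92 for ethanol in wild-type mice, 1489 and 487 for genotype on the control and ethanol diets, 17 for ethanol averaged and 1577 for genotype averaged. With an estimated correlation 0 lists passed for ethanol in wild-type mice, ethanol in null mice, genotype on the control diet, genotype on the ethanol diet, ethanol averaged and genotype averaged, where 4, 4, 9, 7, 6 and 10 passed with the preset correlation. Near Ppard the odds ratio was 1.326 over 400 genes on each side and 1.281 over the whole chromosome, and 0.695 over 100 genes on each side.

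With 1 array left out in turn, calls ranged from 0 to 812 for ethanol in wild-type mice, 0 to 3 for ethanol in null mice, 192 to 1306 for genotype on the control diet, 108 to 319 for genotype on the ethanol diet, 0 to 84 for the interaction, 0 to 293 for ethanol averaged and 621 to 1317 for genotype averaged. The highest count came without wild-type control 2 except for ethanol in null mice (without null control 3) and genotype on the ethanol diet (without null control 1). The lowest came without wild-type ethanol 2, without null control 2 and without wild-type ethanol 3 for ethanol in wild-type mice, genotype on the control diet and both genotype on the ethanol diet and genotype averaged. For the other 3 comparisons several arrays gave 0. Called lists ranged from 2 to 9, 1 to 10, 4 to 12, 5 to 8, 0 to 5, 3 to 10 and 6 to 14 in the same order. The ethanol correlation ranged from -0.083 to 0.06 and the genotype correlation from 0.432 to 0.532. The genotype difference of Ppard ranged from 0.05 to 0.14. An arm with an array left out has 2 arrays, and its spread is taken as that of the other groups.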

Other observations

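The test of an ethanol response common to both genotypes was chosen before its result was seen.

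Genotype averaged over the diets, with 982 of 14013 genes called in all, had called members in smaller lists. The one-carbon genes Cth at -0.71 ± 0.10 and Ahcy at -0.39 ± 0.07 fell (2 of 16; 3 adjusted over the list alone), and the phosphatase gene Alpl, 1 of 5 vitamin B6 genes, rose by 0.59 ± 0.07 (2 higher and 1 lower adjusted over the list alone). Of 15 gluconeogenesis and glycolysis genes 3 rose (5 adjusted over the list alone), Pklr, the glucose transporter gene Slc2a2 at 0.39 ± 0.08 and Pfkfb3 at 1.05 ± 0.26, and of 16 retinoid genes 1 rose, Cyp26a1 at 0.92 ± 0.22 (1 adjusted over the list alone). Of 15 CAR targets 1 rose and 1 fell (2 and 1 adjusted over the list alone), and of 8 female-biased genes 1 rose, Cyp2a4 at 1.48 ± 0.23, and 1 fell, Cyp2b9 (the same adjusted over the list alone). Of 21 acute phase genes 2 fell in either count, Saa2 and Saa4. The number that fell with 1 array left out ranged from 1 to 3 for acute phase genes and from 2 to 3 for one-carbon genes, and the number that rose ranged from 2 to 4 for gluconeogenesis and glycolysis.

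A single member passed in either count, adjusted over all genes or adjusted over the list alone, in the lists of AhR targets (1 of 4, Lgals3 at -0.31 ± 0.08), NRF2 genes (1 of 13, Hmox1 at -0.38 ± 0.11), beta-oxidation (1 of 18, Acads at 0.30 ± 0.07), oxidative phosphorylation (1 of 24, Ndufb8 at 0.25 ± 0.06), bile acid genes (1 of 15, Cyp7b1 at -0.60 ± 0.15), pericentral markers (1 of 16, Oat at -0.49 ± 0.10) and metallothioneins and iron (1 of 12, Tfrc). Of 16 autophagy genes 1 rose, Ulk1 at 0.42 ± 0.08 (2 higher and 1 lower adjusted over the list alone), and of 16 proliferation genes 1 rose, Rrm2 at 0.70 ± 0.11, and 1 fell, Mcm6 at -0.56 ± 0.07 (2 and 1 adjusted over the list alone). Limma called 0 members in either count in the lists of ethanol and acetaldehyde metabolism (11), PXR targets (11) and p53 targets (11), where 3005 of all genes had an unadjusted p under 0.05. With 1 array left out, the numbers that rose or fell in the lists with a single member called ranged from 0 to 2, and from 0 to 1 in the 3 lists without any. Second probe sets of Mid1, Cdh1, Lpl, Rrm2, Ahcy and Alpl were dimmer than those used, which the choice of the brightest set fixes. Those of Mid1, Cdh1, Lpl and Rrm2 lay below the filter (5.61 to 5.72). That of Ahcy had means of 7.95 and 7.90 in wild-type and 7.70 and 7.86 in null livers (control, ethanol), a smaller fall. That of Alpl had means of 6.35 and 6.58 in wild-type and 6.80 and 6.92 in null livers, a smaller rise on average.

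Wild-type control 2 decided the count for ethanol in wild-type mice, which was 13 with it and 812 without it. An ethanol response common to both genotypes may be hidden by this array, and would show as the same sign in the null arrays, which share none with it. The share with the same sign was 58.1%, where the general shift of all genes in null arrays (38.1% rose and 61.9% fell) alone would give 52.6% for 316 higher and 496 lower genes. Of the higher genes (median 0.51 in wild-type arrays) 33.9% rose in null arrays (median -0.07, upper quartile 0.03), and of the lower genes (median -0.46) 73.6% fell there (median -0.07, lower quartile -0.15). A response of like size in null mice was thus not seen, and whether a smaller one is shared stays open. Of the 812 genes 48 were snoRNAs.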
